A study of Mus musculus with 2 samples.

How the data were processed

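The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) for H3K4me1, histone H3 with 1 methyl group on lysine 4, a mark found at enhancers and beside promoters. The tissue was midbrain of mouse embryos of strain B6NCrl at embryonic day 13.5, pooled over both sexes per the labels. There were 2 samples in 1 group, which the labels number as biological replicates 1 and 2, and no second condition. The labels give a size range of 300 to 500 for each library and name a possible control experiment, which was not analysed here.

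The analysis started from 4 peak lists on the mm10 assembly. Per the text records deposited with the samples, there was 1 list for each replicate, 1 list called on both replicates together (the pooled list), and 1 list of replicated peaks derived from the other 3. The aligner, the peak caller, their versions, the calling threshold and the rule for a replicated peak are not given in the sources used here. In each list the authors give an enrichment for every peak, a ratio over a background that is not named for the peaks. The deposited lists also hold the −log10 of the p-value and of the q-value of each peak and the position of its summit. These values are the authors' own and were used only to describe, rank or filter peaks within a list. The files hold no read counts, so the sequencing depth of each library is unknown, and no interval that needs depth is given. The lowest −log10 p was 2.01 in both replicate lists, 2.03 in the pooled list and 2.03 in the replicated list. A higher depth gives more and longer peaks, so counts of peaks and covered bases are compared with care and mostly within a list.

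Coordinates were set on the GRCm38.p6 genome, the build that mm10 names, with the GENCODE release M21 annotation. On all 21 chromosomes (1 to 19, X and Y) the last peak and the last annotated base lay within the chromosome length. Protein-coding genes were taken once per symbol, 21911 in all, with the 5′ end of the gene as its transcription start site (TSS). Positions are printed from 1. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0, pysam 0.24.0, bedtools 2.31.1, samtools 1.23.1 and matplotlib 3.10.9 were used.

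The comparison that the design implies is replicate against replicate. Peaks of the replicates were called shared when they overlapped by at least 1 bp. The same share was computed after 100 seeded shuffles of the other list within chromosomes, outside assembly gaps. For each gene, the percent of the window 50 kb either side of the TSS that peaks cover was computed from each list. The replicates gave a mean and a standard deviation (SD, n = 2) for each gene. The SD measures the spread between these 2 samples.

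A total of 26 gene lists was fixed for cell types and regions the dissected tissue could hold, for neighbouring brain regions and for tissues it should lack. These lists and the motifs were fixed before the data were examined, as were the tests and alternative settings except those that the text gives as chosen later. The median of a list in the replicated peaks was set against 10000 random lists of as many genes, matched on gene length (5 bins) and on the number of TSSs in the window (5 bins). The permutation p is two-sided, with Benjamini-Hochberg adjustment over the 26 lists and a threshold of 0.05. The smallest unadjusted p that the random lists can give is 2.00e-04. Genes are not replicates, so a percentile describes these 2 libraries. A total of 11 genes stands on more than 1 list.

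Peak bases were put into promoter (1 kb either side of any annotated TSS), exon, intron or intergenic sequence, in that order of priority, and compared with the genome and with 100 shuffles. The share of TSSs covered was read at 100 bp steps up to 5 kb either side. Replicated peaks within 3 kb of each other were joined into domains and ranked by covered bases. For 18 consensus motifs, occurrences on both strands were counted in peaks over 1 kb from any TSS. They were divided by the same density in control regions of equal width and GC content (bins of 2 percentage points) at least 2 kb from every peak, over 20 seeded draws. A control was found for 95.0% of the distal replicated peaks.

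Named genes follow a rule. They are the genes nearest to the 10 strongest domains, the 10 genes with the highest mean window value (genes with TSSs within 50 kb counted once), and the 2 highest members and the lowest member of each list described. A gene named outside this rule is said to be so.

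The computations of replicate overlap, gene lists, TSS profiles, domains and motifs were tested on data with known answers. For the gene lists, shifts were planted in the observed window values, and the other tests used simulated peaks or sequence. The annotation classes and the later tests of explanations were not tested in this way. In the test of replicate overlap, 40000 simulated peaks with 60.00% planted as shared gave 60.62%. In the gene list test on 21911 genes, 6.00% of 100 unshifted lists of 16 genes had an unadjusted permutation p under 0.05. With a planted shift of 3 percentage points 19.0% of the lists did, with 6 points 65.0% and with 12 points 100%. A list that was not called can thus differ by several points. For the TSS profile, 39.67% of 21911 TSSs were given a downstream peak and the highest value found was 40.12%. In the motif test, 462 planted motifs in 998 simulated regions gave 464 motifs beyond those in controls.

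Alternatives covered the minimum overlap, the authors' −log10 q (2 or more) and enrichment (3 or more), the window (10 kb and 100 kb), the promoter width, the TSS set, the matching of random lists, the joining distance, the motif controls and each replicate alone. Peaks on unplaced scaffolds (4 in each replicate list, 6 in the pooled list and 3 in the replicated list) were left out of the analyses that use the reference. The matched input and any other tissue or stage were not analysed here.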

Results

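H3K4me1 peaks of midbrain from mouse embryos at embryonic day 13.5 were available for 2 biological replicates. The labels name no second condition, so the design compares the replicates with each other and describes where in the genome the mark lay in both. Replicate 1 had 202425 peaks covering 119.6 Mb, or 4.52% of the genome outside assembly gaps. Replicate 2 had 189379 peaks covering 114.0 Mb, or 4.30%. The median peak was 364 bp wide in replicate 1 and 378 bp in replicate 2, and the median enrichment, as the authors give it, was 3.13 and 3.12. The depth of the libraries is unknown, because the files hold peaks and no read counts.

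The strongest H3K4me1 sites were found in both replicates, while weak sites often were not. Of the replicate 1 peaks, 71% (143811 of 202425) were overlapped by a peak of replicate 2, against 8.97% (range 8.79 to 9.15%) when the positions of the second list were shuffled. Of the replicate 2 peaks, 76.4% (144755 of 189379) were overlapped, against 9.55% (range 9.37 to 9.74%) after shuffling. Among the 10% of peaks with the highest enrichment, 99.9% of replicate 1 and 100% of replicate 2 peaks were shared. Among the 10% with the lowest enrichment, 44.2% and 58.7% were. The median width was 234 bp in the lowest 10% and 1419 bp in the highest 10% of replicate 1, and 259 and 1378 bp in replicate 2. Wider peaks are overlapped more easily, and the shuffles were not split by enrichment, so enrichment and width were not separated. Replicate 1 peaks without a partner had a median enrichment of 2.68 and a median width of 236 bp, against 3.45 and 486 bp for shared peaks. In replicate 2 these values were 2.68 and 242 bp against 3.35 and 476 bp. The shared bases came to 86.17 Mb, 58.5% of all bases covered in either replicate. Only 2 peaks had the same start and end in both lists, so the lists are not copies of each other. When an overlap of at least 50% of the peak was asked for, the shares were 61.5% and 67.1%.

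**Figure D1:**
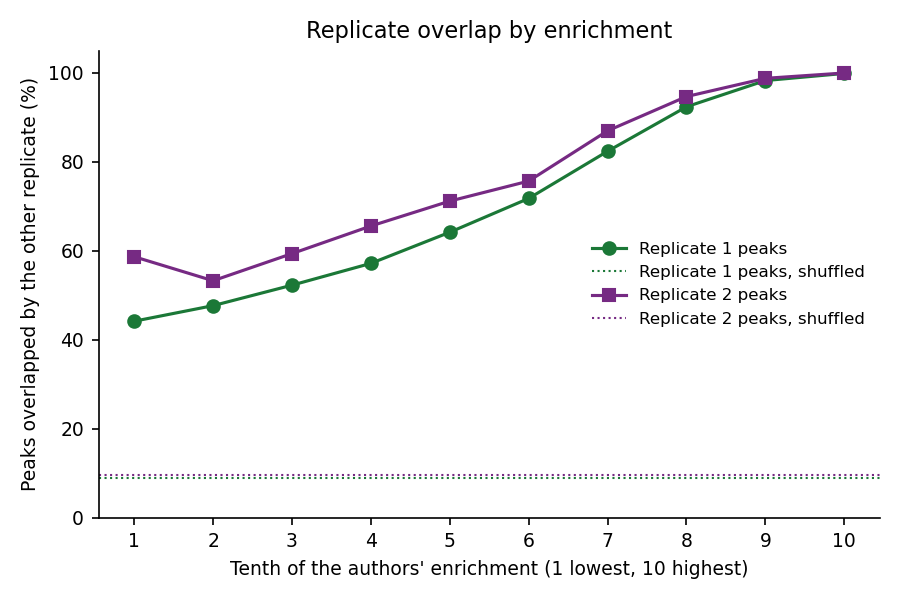
Percent of peaks of replicate 1 (circles) and replicate 2 (squares) overlapped by a peak of the other replicate, in 10 equal bins of the authors' enrichment within each list; dotted lines give the mean of 100 shuffles. The share runs from 44.2% in the lowest bin of replicate 1 to 99.9% in its highest bin. In every bin both lists lie above the shuffled 8.97% and 9.55%, which were computed over all bins together.

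The replicated list of the authors held 135928 peaks over 131.5 Mb, 4.97% of the genome. All of them were peaks of the pooled list with the same position and values, and they made up 64.9% of it. Replicated peaks had a median enrichment of 3.29 and a median width of 679 bp. The 73573 pooled peaks outside the list had 2.28 and 248 bp. Of those outside it, 50425 touched a peak of 1 replicate, 22178 touched none and 970 touched peaks of both. All 118119 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were in the list, and 17809 peaks of the list lacked such an overlap. Replicate 1 covered at least 50% of the length of 87.0% of replicated peaks, and replicate 2 did so for 82.6%. The analyses below use the replicated list, with the mean and SD of the replicates' own lists beside it. Values of the replicated list can lie above those of both replicates. It covered 17.6% of TSSs, for example, against 15.5% in replicate 1 and 15.4% in replicate 2. The SD is thus the spread between the replicates and not an error of the replicated value. Medians of gene lists come from the replicated list unless given for the replicates, while values of named genes are means over the replicates.

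The marked parts of the genome were spread unevenly over chromosomes. Autosomes carried 43.8 (chromosome 14) to 80.0 (chromosome 11) replicated peaks per Mb. The X chromosome carried 8.23 per Mb, with 0.538% ± 0.018 (SD, n = 2) of its length covered by replicate peaks. On chromosome 11, the most densely marked, 7.56% ± 0.23 was covered. The Y chromosome carried 0 replicated peaks.

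Around protein-coding genes the replicates gave nearly the same values. The percent of the window 50 kb either side of the TSS that was covered had a Pearson r of 0.994 and a Spearman rho of 0.992 across 21911 genes, which are not independent replicates. The median gene had 5.85% of its window covered by the replicated list, 10% of genes had 20.0% or more, and 3753 genes (17.1%) had none. The median SD between replicates was 0.30 percentage points. Differences between genes of several points were thus larger than the spread between the replicates for most genes.

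The 10 genes with the most densely marked windows had 52.0% to 66.4% covered. Pipox, an enzyme of pipecolic acid breakdown, had the highest value, 66.4% ± 0.51 (SD, n = 2), and its window also holds another protein-coding TSS. Flrt1, a leucine-rich repeat transmembrane protein, followed with 65.5% ± 0.79. The transcriptional coregulator Tcf20 had 60.1% ± 1.4. Efna2, an ephrin ligand, had 56.7% ± 0.025, and the Eph receptor Ephb2 had 55.7% ± 1.0. Ccdc85c had 55.1% ± 0.74, and the nuclear receptor corepressor Ncor2 had 54.0% ± 0.53. Srgap3, a GTPase-activating protein of the Slit-Robo pathway, had 52.2% ± 1.5. Bahcc1 had 52.1% ± 0.34 and Ssbp3, a cofactor of LIM homeodomain complexes, 52.0% ± 0.10.

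Joined into domains, replicated peaks formed 67720 regions, of which 37278 held a single peak. The 1185 domains that covered at least 10 kb held 15.7% of all replicated bases. The strongest domain lay within the gene body of Msi2, an RNA-binding protein of neural progenitors, on chromosome 11 from 88387498 to 88667446 (mm10). Its 84 peaks covered 224 kb, and replicate peaks covered 208 kb ± 4.7 (SD, n = 2). The domain at the TSS and gene body of Ephb2 (chromosome 4, 136698241 to 136841265) covered 117 kb, with 107 kb ± 0.16 in the replicates. The domain in Ssbp3 (chromosome 4, 106913234 to 107027428) covered 107 kb, with 102 kb ± 0.53. Those in Gse1 (chromosome 8, 120260559 to 120400608) and Srgap3 (chromosome 6, 112827366 to 112950573) covered 100 kb and 96.5 kb. A second domain in the body of Gse1 (chromosome 8, 120483667 to 120576421) covered 82.9 kb. By the 5′ end of the gene its nearest gene was Gins2, 12.9 kb away. The seventh domain (chromosome 8, 108690594 to 108791557) covered 81.9 kb within the gene Zfhx3, a zinc finger homeobox gene named here for its position. The rule gave Pmfbp1, whose 5′ end lies 702 kb away. In a check chosen after the data were seen, TSSs of all protein-coding transcripts were used. By these, the domain within Zfhx3 held a TSS of Zfhx3, and the second domain in Gse1 held a TSS of Gse1. The domains at Ebf3 (chromosome 7, 137236691 to 137323271), Rere (chromosome 4, 150366398 to 150474993) and Zmiz1 (chromosome 14, 25445322 to 25534703) covered 75.3, 74.0 and 68.0 kb. Ebf3 is a transcription factor of neuronal differentiation, and Rere and Zmiz1 are transcriptional coregulators. Joining peaks over a longer distance than 3 kb kept 5 of these 10 regions among the 10 strongest.

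**Figure D2:**
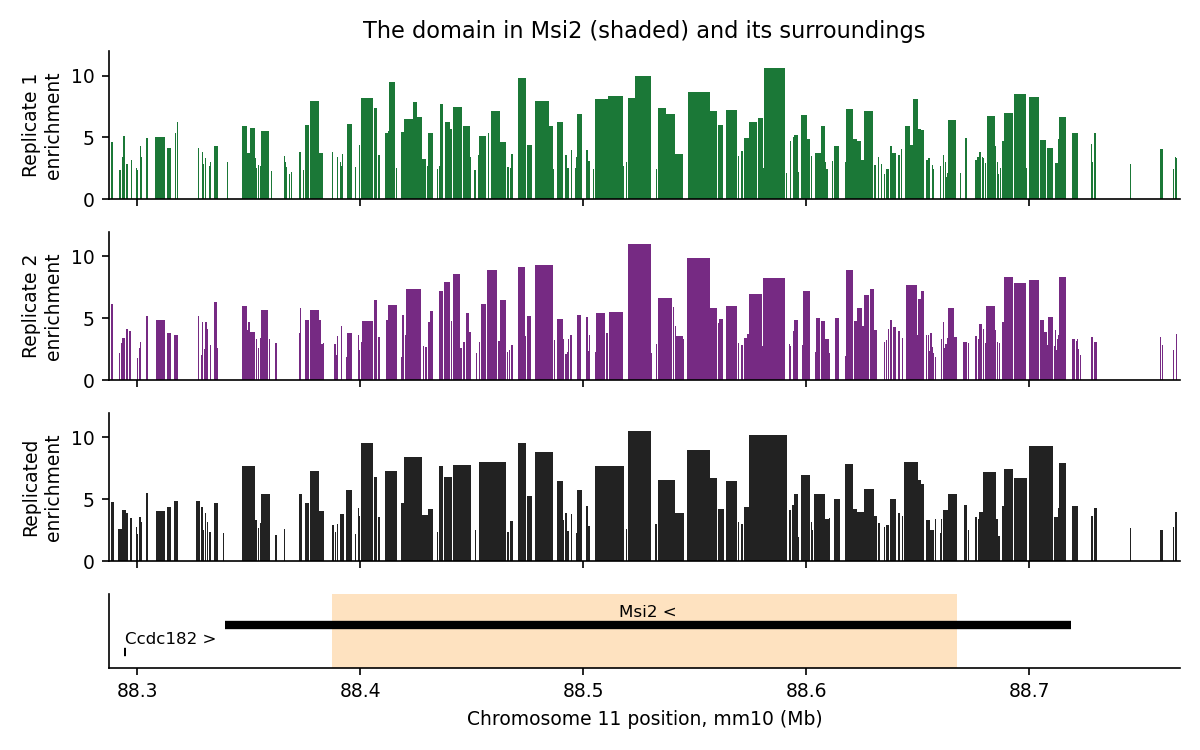
Peaks around the strongest domain, on chromosome 11 (mm10, Mb); bar widths are peak widths and heights the authors' enrichment in replicate 1, replicate 2 and the replicated list, with genes (arrowheads give the strand) and the domain shaded below. The shaded domain, 280 kb long, holds 84 replicated peaks and lies inside Msi2.

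H3K4me1 lay beside promoters and within genes more than the genome average, and less between genes. Promoters, within 1 kb of any annotated TSS, held 19.2% of replicated bases and 6.05% of the genome, a ratio of 3.18 (3.17 ± 0.041 over the replicates, SD, n = 2). Shuffled peaks had 6.38% in promoters (range 6.22 to 6.5%). Introns held 53.2% of bases, 1.39 times their share of the genome, and exons 4.52%, 1.42 times. Intergenic sequence held 23.0% of bases, 0.439 times its share (0.436 ± 0.0045 over the replicates). Shuffled peaks had 49.8% there (range 49.5 to 50.2%). Most peaks were far from the 5′ ends of protein-coding genes, since 42.1% lay 10 to 100 kb and 28.2% over 100 kb from the nearest one. Other annotated TSSs were not counted in this distance. The median distance was 37.3 kb. With 1 TSS per protein-coding gene in place of all annotated TSSs, the promoter ratio was 5.60.

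Over all genes, the TSS was marked less often than its flanks, but this held mainly at CpG-rich promoters. A peak covered the TSS in 15.5% ± 0.061 (SD, n = 2) of 21911 genes. Upstream the share rose to 27.3% ± 0.75, and downstream to 39.7% ± 0.47, at 1000 bp in replicate 1 and 1100 bp in replicate 2. At 5 kb, as the mean of the upstream and downstream positions, it was 7.54% ± 0.20. The downstream flank stood 24.2 percentage points ± 0.41 above the TSS, far more than the spread between the replicates. In a split chosen after the data were seen, the difference in the replicated list was 58.8 points at 9725 CpG-rich promoters and 1.80 points at the other 12186.

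**Figure D3:**
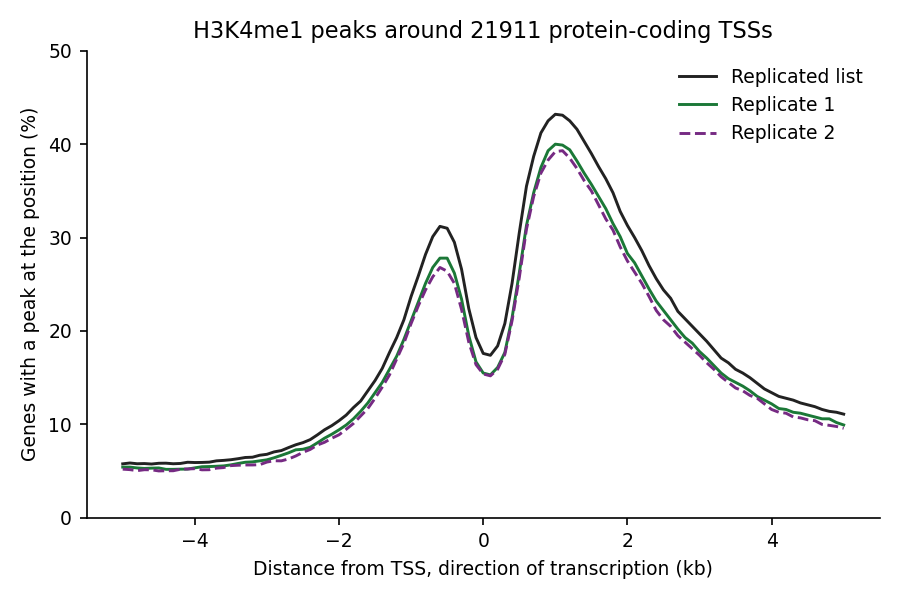
Percent of 21911 protein-coding genes with a peak at each position up to 5 kb from the TSS, in the direction of transcription, for the replicated list, replicate 1 and replicate 2. In the replicated list the share is 17.6% at the TSS, 31.2% upstream and 43.2% downstream.

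Genes that pattern the midbrain and the isthmus, the boundary with the hindbrain, had the highest median of the 26 lists in the window of 50 kb. In a window of 10 kb their median of 36.9% lay below those of neural progenitor (45.5%), Notch pathway (41.6%) and GABAergic (38.3%) genes. All 19 members lay above the median of all genes. Their median window was 23.3% covered by the replicated list, against 3.88% for matched random lists (central 95% of lists 1.35 to 7.99%), and 19.6% ± 0.27 (SD, n = 2) by the replicates. Pax7, a homeobox factor of the dorsal midbrain (chromosome 4, 139737062 to 139833528), had 38.3% ± 2.8. Lmx1b, a LIM homeobox factor of the isthmus (chromosome 2, 33560965 to 33640511), had 28.0% ± 0.75. The lowest member was Pax8 with 6.52% ± 0.30. The list stood above all 10000 random lists, with an adjusted permutation p of 7.43e-04. The random lists here and below were not matched on the CpG content of promoters. At the highest downstream position, replicate peaks covered 68.3% of CpG-rich promoters and 19.1% of the others. Whether CpG content accounts for the place of any list was not tested.

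Progenitor and signalling genes also had dense marking. Neural progenitor and radial glia genes had a median of 19.7%, and 15 of 17 lay above the median of all genes. Notch1, the Notch receptor, had 41.0% ± 0.90 and Nes, the intermediate filament nestin, 34.9% ± 0.23, while the X-linked Sox3 had 3.97% ± 0.62. Notch pathway genes had a median of 18.9% (16 of 18 above). Lfng, which modifies Notch, had 30.2% ± 0.015, and Rbpj, its DNA-binding partner, had the lowest value of the list at 0.369% ± 0.18. Notch1 stands on both of these lists. Axon guidance genes had a median of 16.4% (22 of 31 above), with Efna2 at 56.7% ± 0.025, Sema3f at 37.7% ± 1.3 and Robo1, a receptor for Slit, at 1.03% ± 0.18. The list of Wnt ligands and receptors had 15.5% (19 of 23 above), with Axin2 at 33.8% ± 0.094, Lef1 at 28.2% ± 0.77 and Rspo2 at 2.09% ± 0.17. It also holds pathway members that are neither ligand nor receptor, among them Axin2 and Lef1. All 4 lists stood above matched random lists, each with an adjusted permutation p of 7.43e-04.

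Lists of neuronal and glial types also stood above matched random lists. Pan-neuronal genes had a median of 15.8% (15 of 18 above the median of all genes, adjusted permutation p = 0.00130). Rbfox3, which encodes the neuronal nuclear antigen NeuN, had 33.6% ± 0.84, Ncam1 21.4% ± 2.7 and Elavl4 2.52% ± 0.37. Midbrain GABAergic genes had a median of 13.9% (14 of 15 above, adjusted permutation p = 0.00231), led by Zfpm1 (34.7% ± 1.5), a cofactor of GATA factors, and Lhx1 (28.7% ± 0.15), with Zfpm2 lowest at 2.64% ± 0.0035. Oligodendrocyte and astrocyte genes had 14.4% (12 of 16 above, adjusted permutation p = 0.00709). Their highest members were the neighbouring genes Olig1 (23.0% ± 0.35) and Olig2 (18.4% ± 0.19), and the lowest was Plp1 (1.65% ± 0.40), a myelin gene on the X chromosome. In a window of 10 kb this list was not called (adjusted permutation p = 0.128, range over its alternatives 0.00607 to 0.128). Glutamatergic genes had 11.8% (11 of 12 above, adjusted permutation p = 0.0134), with Tcf7l2 at 36.8% ± 1.0, Neurog1 at 28.2% ± 1.0 and Tfap2b at 4.42% ± 0.88. This list was not called in a window of 100 kb (adjusted permutation p = 0.0657) or against unmatched random lists (0.120), with a range over its alternatives of 6.50e-04 to 0.120.

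Midbrain dopaminergic genes had a lower median, 9.84%, and 10 of 16 lay above the median of all genes (adjusted permutation p = 0.0160). The proneural factor Neurog2 had 15.3% ± 1.5 and Ddc, aromatic amino acid decarboxylase, 13.9% ± 0.43. Aldh1a1, a retinaldehyde dehydrogenase of a subset of these neurons, had 0.0960% ± 0.14. The call was lost in a window of 10 kb (adjusted permutation p = 0.0897), in a window of 100 kb (0.303) and against unmatched random lists (0.202). Over its alternatives the value ran from 0.0115 to 0.303. Genes of the ventral midline and motor nuclei had a median of 7.03% and were not called (adjusted permutation p = 0.121). Phox2a, a factor of oculomotor neurons, had 10.9% ± 0.63, Nkx6-2 10.7% ± 1.3 and Nkx2-9 1.78% ± 0.27. In a window of 10 kb this list was called (adjusted permutation p = 0.00563, range over its alternatives 0.00563 to 0.763).

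Genes of neighbouring brain regions were not tested against the midbrain lists. Forebrain genes had a median of 8.56% and 16 of 20 lay above the median of all genes (adjusted permutation p = 0.00709). Bcl11b, a zinc finger factor of cortical neurons, had 39.3% ± 0.63, Lhx2 19.2% ± 0.91 and Six6 2.66% ± 0.21. Against unmatched random lists the forebrain list was not called (adjusted permutation p = 0.320, range over its alternatives 0.00156 to 0.320). Hindbrain genes had 7.67% and were not called (adjusted permutation p = 0.0789), although they were in a window of 10 kb (adjusted permutation p = 0.00600, range over its alternatives 0.00600 to 0.591). Lmx1b, which is also on the midbrain list, had 28.0% ± 0.75, Fev, a factor of serotonergic neurons, 16.2% ± 0.17, and the serotonin transporter Slc6a4 2.65% ± 0.13. The 39 Hox genes, which pattern the hindbrain and spinal cord, had a median of 5.78% against 10.1% for matched random lists and were not called (adjusted permutation p = 0.109). With 1 member per 200 kb, fewer Hox genes were left than the 5 needed for a test. Many of their windows thus overlap, while the permutation takes the members as separate genes, so its p carries little weight here. Against unmatched random lists the Hox list stood at the percentile 48.54. Hoxd8 had 11.7% ± 0.47, Hoxd9 9.96% ± 0.44 and Hoxb13 0.795% ± 0.50.

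Most lists of other tissues were not called. Endothelial genes had a median of 5.02% (adjusted permutation p = 0.993), with Eng at 15.6% ± 0.12, Egfl7 at 15.5% ± 0.36 and Tek at 0.490% ± 0.076. Macrophage and microglia genes had 6.99% (adjusted permutation p = 0.611). Their highest members, the complement genes C1qb (27.9% ± 0.46) and C1qa (26.3% ± 1.6), lie within 100 kb of the Ephb2 domain, and Adgre1 had 0%. Mesenchyme, meninges and pericyte genes had 5.5% (adjusted permutation p = 0.454), heart genes 8.06% (0.189), liver genes 3.41% (0.266) and pluripotency and germ cell genes 3.17% (0.454). The highest members of these lists were Pdgfrb (14.7% ± 0.23) and Foxc2 (9.27% ± 0.84) in mesenchyme, Tnni3 (14.8% ± 0.62) and Myh7 (13.6% ± 0.17) in heart, Apoa2 (17.4% ± 0.34) and Foxa3 (14.8% ± 0.24) in liver, and Mael (16% ± 0.11) and Pou5f1 (8.18% ± 1.6) in germ cells. The lowest were Lum and Serpina1a at 0%, Tbx5 at 2.10% ± 0.36 and Zfp42 at 0.508% ± 0.11. Erythroid genes had 1.74% (adjusted permutation p = 0.0725), with Nfe2 at 29.6% ± 0.93, Epor at 19.3% ± 1.2 and the embryonic globin Hbb-y at 0%. Epidermal genes had 0.948% (adjusted permutation p = 0.0789), with Grhl3 at 22.9% ± 0.61, Sfn at 8.11% ± 0.32 and Ivl at 0%. Against unmatched random lists the epidermal list was called below (adjusted permutation p = 0.0377, range over its alternatives 0.0377 to 0.683).

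Skeletal muscle and housekeeping genes stood above random lists, and chemosensory receptors below. Skeletal muscle genes had a median of 10.2% (10 of 14 above the median of all genes, adjusted permutation p = 0.0239). Pax7, which is also on the midbrain list, had 38.3% ± 2.8, the intermediate filament gene Des 23.0% ± 0.19 and the myosin Myh8 0.144% ± 0.20. The call was lost in a window of 10 kb (adjusted permutation p = 0.667), against unmatched random lists (0.202) and without Pax7 (0.0728), a setting chosen after the data were seen. Without Pax7 the median was 9.36% and the percentile among random lists 97.93, against 99.32 with it. Over its alternatives the adjusted permutation p ran from 0.0144 to 0.667. Housekeeping genes had 13.6% (17 of 20 above, adjusted permutation p = 0.0208), with Rps18 at 23.8% ± 1.1, Vcp at 21.5% ± 0.17 and the X-linked Hprt at 0.887% ± 0.41. With the peaks of replicate 2 alone the adjusted permutation p of this list was 0.0510, with a range over its alternatives of 0.00331 to 0.0510. Of 1092 olfactory receptor genes 898 had no replicated peak in the window, as did 297 of 326 vomeronasal receptor genes. Both medians were 0%, against 7.44% and 5.28% for matched random lists (adjusted permutation p = 7.43e-04 for each). In a window of 10 kb the olfactory receptors were not called (adjusted permutation p = 1.00), but the test could not decide there. Their median was 0%, the lowest value possible, and many matched random lists had it too. In the other alternatives the adjusted permutation p ran from 5.56e-04 to 0.00104.

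**Figure D4:**
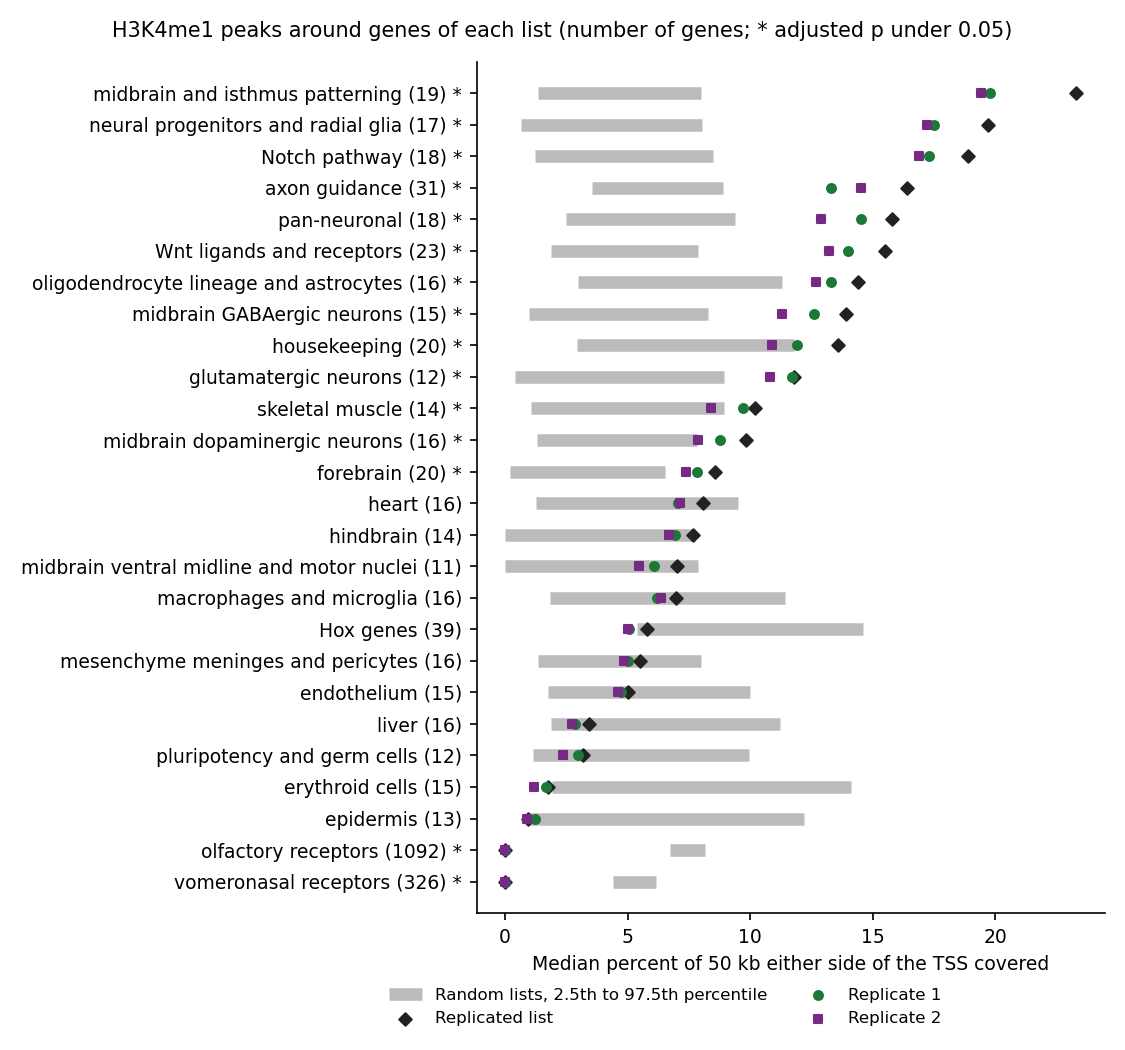
Median percent of the window 50 kb either side of the TSS covered by peaks, for each of the 26 gene lists (number of genes in brackets), in the replicated list (diamonds), replicate 1 (circles) and replicate 2 (squares); grey bars hold the central 95% of 10000 matched random lists and an asterisk marks an adjusted permutation p under 0.05. Midbrain and isthmus patterning genes lie highest at 23.3%, and olfactory and vomeronasal receptors at 0%.

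Several motifs of factor families known from neural development were denser in peaks far from promoters than in control sequence of the same width and GC content. The palindromic motif of nuclear factor I (NFI), with 185 occurrences, was 4.03 times as dense in distal replicated peaks (range over 20 control draws 3.22 to 5.0) and 3.77 ± 0.18 (SD, n = 2) over the replicates. The regulatory factor X (RFX) motif was 1.90 times as dense (range 1.85 to 1.99), the POU octamer 1.74 times (range 1.68 to 1.80) and the homeodomain core 1.66 times (range 1.63 to 1.69). The LHX homeodomain motif had 1.66 (range 1.61 to 1.75) and the E-box CAGCTG 1.32 (range 1.31 to 1.33). SOX (1.15), OTX (1.08) and the E-box CAGATG (1.06) were closer to the controls. Among motifs of other tissues, MEF2, a family active in muscle and neurons, had 1.70 (range 1.60 to 1.89), GATA 1.13 and HNF1 1.46, whose range starts at 0.964. The myeloid PU.1 motif had 0.887 (range 0.853 to 0.909) and the liver motif HNF4 0.982 (range 0.920 to 1.05). The motif of CTCF, a factor of chromatin loops, had 0.835 (range 0.766 to 0.905). The other general motifs had 1.56 (NRF1, range 1.26 to 2.68), 1.11 (TEAD) and 1.02 (AP-1). Beside controls 5 kb from each peak, not matched on GC content, the direction turned for CTCF (1.33), PU.1 (1.01), GATA (0.896), OTX (0.973) and HNF1 (0.795), so none of these 5 is called denser or sparser here. With those controls the homeodomain ratio was 1.05 and MEF2 1.02. As a check chosen after the data were seen, 5 permuted consensus sequences of the same letters gave at most 1.08 for RFX, 1.35 for NFI and 1.31 for both the homeodomain and MEF2 motifs. In the central 200 bp of gaps of 100 to 1000 bp between neighbouring replicated peaks, the CTCF motif was 6.62 times as dense as in controls (range 4.47 to 9.79). NFI had 1 occurrence there.

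**Figure D5:**
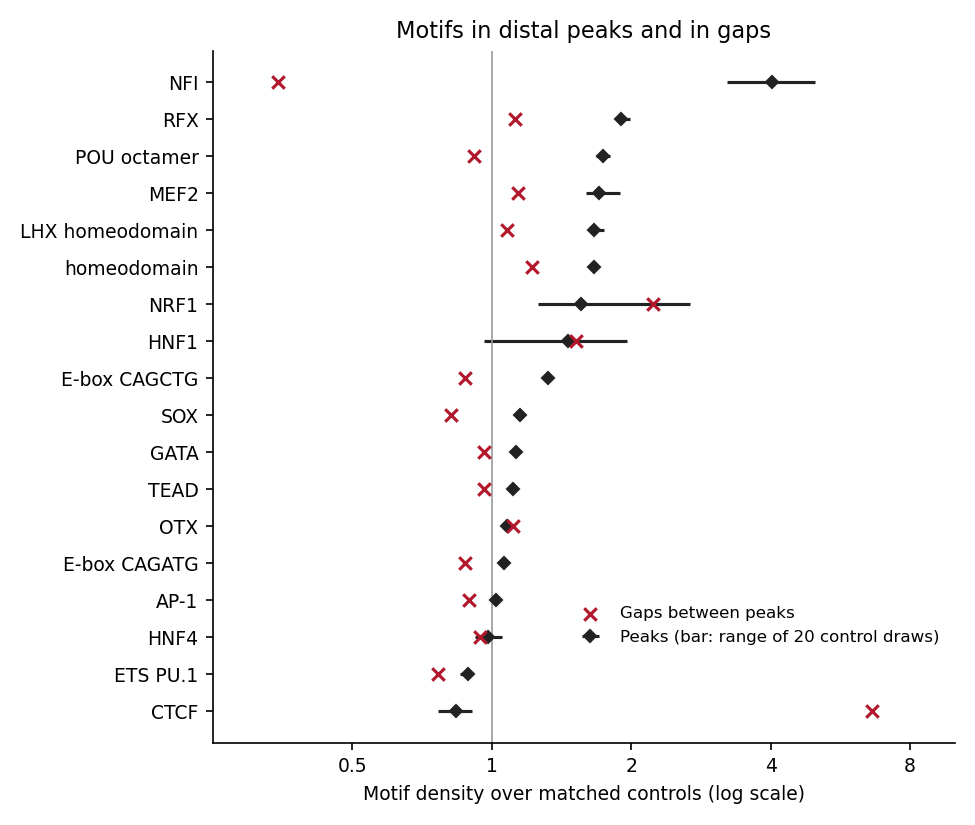
Density of 18 consensus motifs in distal replicated peaks over matched controls (diamonds, bars for the range of 20 control draws) and in the central 200 bp of gaps between peaks (crosses), on a log axis. NFI lies highest in peaks at 4.03, and CTCF highest in gaps at 6.62, while the NFI cross rests on 1 occurrence.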

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

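No tests of explanations were run for the result below. It was set apart because it lies on a scaffold that the gene, annotation, domain and motif analyses left out, although the overlap of the replicates counted it, and because its count in each replicate is above the 3 that a count of 0 allows. An unplaced scaffold assigned to the X chromosome carried 4 peaks in replicate 1, 4 in replicate 2, 5 in the pooled list and 3, not above that limit, in the replicated list.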

How the results depend on the processing

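The splits by CpG content, the muscle list without Pax7, the lists of autosomal genes alone, the nearest transcript TSS for domains and the soft-masked motifs were chosen only after the result was seen, and the other alternatives were planned. Of the values that answer a comparison, 261 counted as the same, 19 moved, 12 list values lost a call and 3 gained one. A list counted as the same when it kept its side of the threshold. Other values did so when they moved by less than the spread between replicates, and counts when they stayed within 1.5 times the count reported. For a list called in neither setting, a change of direction still counted as the same. Macrophages and microglia, at the percentile 70.63, thus stood at 27.70 with a 10 kb window. Under the rule for counts, the lists called above went from 13 to 9 against unmatched lists and to 11 at 100 kb. Those called below went from 2 to 3 against unmatched lists. Where a value below changed, the cause was not tested. Asking for an overlap of 50% of the peak gave 61.5% for replicate 1 and 67.1% for replicate 2. Counting any overlap of 1 bp, replicate 1 covered 94.9% of replicated peaks and replicate 2 covered 91.9%. The correlation across genes was 0.984 at 10 kb, 0.996 at 100 kb and 0.993 with a −log10 q of 2 or more. The promoter ratio was 2.52 with 2.5 kb promoters and 5.60 with 1 TSS per gene, and the intergenic ratio was 0.421 and 0.445. With 1 replicate left out the intergenic ratio ran from 0.433 to 0.439 and the TSS difference from 23.9 to 24.5 points. The TSS difference was 58.8 points at CpG-rich promoters and 1.80 at others. Exon and intron ratios moved in 8 cases, between 1.06 and 1.71.

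List percentiles that changed side are given by setting. With a 10 kb window, the dopaminergic list stood at 97.25, oligodendrocyte and astrocyte at 95.59 and skeletal muscle at 70.51, none of them called. Olfactory receptors stood at 31.70 and were not called, which left 1 list called below. Their median was 0% there, as in many random lists, so they could not have been called below. Ventral midline (99.88) and hindbrain (99.86) were called there. With 100 kb, dopaminergic (88.92) and glutamatergic (98.24) were not called. Against unmatched lists, dopaminergic (93.80), glutamatergic (96.77), forebrain (89.47) and skeletal muscle (94.13) were not called, and epidermis (0.8600) was called below. Muscle without Pax7 stood at 97.93. Housekeeping ran from 98.54 to 99.20 with 1 replicate left out. Joining peaks over a longer distance kept 5 of the 10 strongest domains.

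In the centre of gaps 3 motifs stood above controls in every draw, against 14 in peaks. The ratios that crossed 1 there were SOX 0.817, CAGCTG 0.873, CAGATG 0.874, POU 0.916, NFI 0.345 (1 occurrence), GATA 0.961, AP-1 0.892, TEAD 0.963 and CTCF 6.62. With flank controls OTX (0.973), GATA (0.896), PU.1 (1.01) and CTCF (1.33) crossed 1, as did HNF1 (0.795), whose range over draws already held 1. Among values of single motifs, classes and genes, 69 moved by more than the spread between replicates, HNF1 with flank controls among them. A further 13 are the other crossings of 1 given above, and 20 counted as the same. The depth of the libraries is unknown, so its effect on weak peaks could not be measured.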

Other observations

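Of the tests in this part, those of gene content, loss of regions and enrichment on the X chromosome, of base composition, soft-masked repeats and gap width for CTCF, the muscle list without Pax7, and the split by CpG content were chosen only after the result was seen. Promoters rich in CpG carried the dip of H3K4me1 at the TSS. They were taken as those with an observed to expected CpG ratio of at least 0.6 and at least 50% G and C within 500 bp of the TSS. At these 9725 promoters a peak covered 12.3% ± 0.30 (SD, n = 2) of TSSs, 45.8% ± 1.2 upstream and 68.3% ± 0.65 downstream. At the other 12186 the values were 18% ± 0.35, 17.5% ± 0.42 and 19.1% ± 0.37. The downstream flank stood 56.0 points ± 0.95 above the TSS at CpG-rich promoters and 1.13 points ± 0.017 at the others.

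The X chromosome carried few peaks. Within 2 kb of the TSSs of 948 X-linked genes, peaks covered 7.75%. For 1000 autosomal lists matched on gene length and on the number of TSSs, they covered 26.8% (range 24.2 to 29.1%). The ratio of 0.290 argues against gene length and TSS number as the whole cause. The lists were not matched on promoter CpG content or on whether genes are active, so other kinds of gene content stay open. The X to autosome density ratio at an enrichment of 4 or more was 0.586 of that at 2 or more (SD 0.019, n = 2). This argues against a loss of whole regions at every enrichment alike, but it rests on the highest minimum alone. At minimums of 2, 2.5 and 3 the ratio was 0.151, 0.161 and 0.147 in replicate 1, and it fell to 0.0865 at 4. In replicate 2 it was 0.151, 0.158 and 0.141, and 0.0906 at 4. A lower enrichment of X peaks at a fixed threshold remains a candidate explanation: X density at 3 or more was 1.46 times (SD 0.028) the autosomal density at 6 or more, but this ratio ran from 0.604 to 1.82 over the minimums tried in the replicates, and the bounds were set with these values in view. Mappability was not tested, and no biological explanation was tested, since the pool of both sexes gives no groups.

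The CTCF motif was dense in the gaps between neighbouring peaks, where 0.468% of gaps (136 of 29066) held it against 0.0585% of controls, with 0.382% against 0.0863% in the gaps of replicate 1 and 0.364% against 0.0900% in those of replicate 2. Permuted consensus sequences gave at most 1.67 in the gaps, which argues against base composition. Motifs outside soft-masked repeats had a ratio of 8.11 (range 5.37 to 12.2), with 6.66 in replicate 1 gaps and 5.22 in replicate 2 gaps, which argues against repeats that split a peak. The motif was 6.87 times as dense in gaps of 100 to under 200 bp as in those of 400 bp or more (exact 95% interval 4.02 to 12.4). The ratio was 3.85 (2.54 to 5.97) in replicate 1 gaps and 3.49 (2.28 to 5.45) in replicate 2 gaps. Gaps of 200 to under 400 bp had 0.0237 motifs per kb in the replicated list, against 0.0547 in the narrowest. In replicate 1 these values were 0.0279 against 0.0303, and in replicate 2 0.0258 against 0.0291. The replicates thus hardly set the narrowest gaps apart from those of 200 to under 400 bp. An occupied site between marked nucleosomes may explain part of the density, but the gap widths do not settle it. No CTCF binding data were analysed, and no biological explanation was tested between groups.

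The skeletal muscle list stood above matched random lists, although the tissue was midbrain. Without Pax7, which the midbrain list also holds, the median was 9.36% in place of 10.2%. The unadjusted permutation p was then 0.0420 and the adjusted value 0.0728, so the list was no longer called. The call was thus sensitive to leaving out a member. A median falls alike whichever member above it is left out, and only Pax7 was. These values thus do not show that Pax7 in particular accounts for the list's place. With a window of 10 kb the list stood at the percentile 70.51, so peaks of other genes in the wide window may account for its place. Cells of muscle as a source were not tested, and no biological explanation was tested.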
